A study of Mus musculus with 2 samples.

How the data were processed

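Single-cell RNA-seq was measured in 2 libraries of mouse skin epidermis, 1 per genotype. The control library came from Involucrin-CreER/Rosa-SmoM2 mice, in which a CreER driven by the involucrin promoter switches on SmoM2, a constitutively active form of the hedgehog receptor component Smoothened. The other library came from mice that carried in addition a Krt14-rtTA driver and a Survivin gain-of-function allele (Survivin GOF). Survivin is encoded by Birc5. Per the labels' protocols, cells were sorted as high for integrin α6, negative for CD34 and positive for YFP. The same protocols state that 10000 cells were loaded per channel on the 10x Chromium 3' system, and they give 8046 cells for the control genotype. How many mice or which sexes contributed is not given in the sources used here.

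The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, made with Cell Ranger 6.1.1 per the file headers. The submitters' processing notes also name R 4.3.0, Seurat 4.2.0 and the mouse build mm10. The matrices hold whole numbers that were not normalized. Each lists 32286 features, the last of them YFP, and 32158 feature identifiers were found in the GENCODE vM21 annotation of that build, from which coordinates were taken. The control matrix held 24844 barcodes with 146216083 UMIs, and the GOF matrix 11438 barcodes with 126329382 UMIs. The lowest barcode total was 502 and 500 UMIs, respectively. The 8046 cells of the labels thus stand beside 24844 barcodes, of which 10993 passed the filter on cells used here and 8187 passed a filter of at least 2000 genes.

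Cells were kept with at least 1500 detected genes and at most 10% of UMIs from mitochondrial genes. Doublets were scored in each library with scrublet at an expected rate of 6%. Its automatic threshold marked almost no barcodes, so the rule fixed for that case was used and the top 6% of scores were removed. All scores at or above that bound were taken out, 753 control barcodes (6.85% of those passing) and 426 GOF barcodes (6.15%). This left 10240 control cells (median 7659 UMIs, 2480 genes) and 6496 GOF cells (median 12316 UMIs, 3403.5 genes). The deeper GOF cells raise every share of cells with a UMI. Such shares were therefore compared after each cell had been thinned at random to 3000 UMIs, with shallower cells left out.

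Counts were log-normalized and clustered with scanpy 1.11.5 under Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, igraph 0.11.9). The steps used 2000 variable genes ranked within each library, 30 principal components, 15 neighbours and Leiden resolution 1. Birc5, mitochondrial, ribosomal protein and sex genes were left out of the clustering. No integration was applied, because library and genotype coincide. Of the 24 clusters, most were named from 17 marker lists. Some, among them clusters 4, 6, 12 and 13, were left unnamed, so the class shares do not cover all cells. All clusters except melanocyte-like cluster 8 and immune-like cluster 20 were pooled as keratinocytes. Clusters 12, 13 and 18 came almost entirely from the control library. Clusters 9, 10, 11 and 14 had YFP between 30.1 and 35.2 CPM in both libraries and are called YFP-high. They were grouped after their YFP values had been seen, and control cells of clusters 22 and 18 had YFP too (36.1 and 15.8 CPM).

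For each population the UMIs were summed per library and scaled to the library total of that population as CPM, and genes were compared by the ratio of GOF to control CPM. With 1 library per genotype there is no test and no replicate check. Ratios carry exact conditional 95% intervals, CPM values exact Poisson intervals and shares exact Clopper-Pearson intervals. All of them cover counting error only and say nothing about the spread between mice. Of 31 gene lists, the median log2 ratio of members with at least 50 pooled UMIs is given with its percentile among 10000 random lists matched on mean expression, as a description of these libraries. Intervals of list medians come from 500 Poisson resamplings of the counts.

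Genes are named by a rule of size. It took the 12 largest ratios in each direction among genes with at least 20 CPM in the higher library and at least 100 pooled UMIs, with the same direction in all of the 6 named epithelial classes holding at least 200 cells per library. Mitochondrial, ribosomal protein, hemoglobin, sex and non-epithelial marker genes and unnamed gene models were left out. Added to these were, for each list, its 4 members with the largest log2 ratio in either direction, and Birc5 and Smo. For the YFP-high clusters the same rule asked for the same direction in each of the 4 clusters. Some genes that the rule selected are not reported here. Gene lists, markers, filters and this rule were fixed before the data were examined.

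Some choices were made afterwards. The whole G2/M list of 51 genes was found in nearly every cell, so a core list of 12 mitotic genes was added. Cells with Y-linked and no Xist UMIs are called male-called, and cells with Xist and no Y-linked UMIs female-called. Comparisons of male-called cells were added because the libraries differed in Xist. Comparisons within the YFP-high clusters, cells with at least 2000 genes and cells outside the 3 control-only clusters were added too.

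Alternatives fixed beforehand were a lenient filter (500 genes, 20% mitochondrial UMIs), a strict filter (2500 genes, 5%), called doublets kept, median-of-ratios scaling, equal weight for every cell, other thinning depths and UMI minimums, other clusterings and a minimum of 10 pooled UMIs. The ratio calculation was tested on simulated counts in which 200 genes differed by known folds. The counts were Poisson draws, as the intervals assume, so this checks the calculation and not whether the intervals hold with extra spread between cells. Over 14574 genes in keratinocytes, 95.7% of the unaltered genes had the true value inside the interval, and the 40 genes set to each of the folds 0.5, 0.667, 1.5, 2 and 4 had median estimates of 0.500, 0.659, 1.50, 1.98 and 3.98. Over 12614 genes in the YFP-high clusters the share was 95.5% and the estimates were 0.495, 0.656, 1.47, 1.94 and 3.94. Over 9314 genes in the sebaceous gland-like class the share was 95.9% and the estimates were 0.502, 0.669, 1.45, 1.95 and 3.85.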

Results

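Keratinocytes sorted for high integrin α6, no CD34 and YFP were profiled by droplet RNA-seq from SmoM2 control mice and from SmoM2 mice with a Survivin gain-of-function (GOF) allele, 1 library each. Kept cells numbered 10240 in the control (100688482 UMIs) and 6496 in the GOF library (101106207 UMIs), of which 10079 and 6318 were keratinocytes. The series addresses whether raised Survivin makes involucrin-lineage cells able to start hedgehog-driven skin tumours. The libraries differed in sex. Xist, the RNA that silences the inactive X chromosome in female cells, stood at 2.71 CPM in control and 554 CPM in GOF keratinocytes. Of the control keratinocytes 7327 were male-called and 30 female-called, against 1805 and 3605 in the GOF library. Values in male-called cells are therefore given beside some of the results. Without replicate libraries, all intervals cover counting error only.

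Birc5, which encodes Survivin, a member of the chromosomal passenger complex and of the inhibitor of apoptosis family, was 14.3-fold higher in GOF keratinocytes (95% interval 13.9 to 14.7). Its level was 55.2 CPM in the control and 790 CPM in the GOF library. Birc5 (ENSMUSG00000017716) lies on chromosome 11 at 117849251 to 117855743 in mm10 and is protein-coding. The gene is normally expressed in mitosis, and in keratinocytes without a UMI of the 12 core mitotic genes the gap was wider, with 6.64 CPM against 733 CPM (log2 ratio 6.79). Infundibulum-like cells had 8.59 and 424 CPM, differentiating keratinocyte-like cells 6.99 and 537 CPM, and sebaceous gland-like cells 10.3 and 1185 CPM. The ratio in basal keratinocyte-like cells, 7.67 against 964 CPM, compares mostly cluster 5 of the control with cluster 2 of the GOF library. In cluster 5, 6 of 17 basal keratinocyte markers were at least 2-fold up, but its 10 leading genes held none of them, 1 bulge marker and 1 fibroblast marker.

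At 3000 UMIs per cell, 12.1% of control and 65.7% of GOF keratinocytes held a Birc5 UMI, against 24.8% and 79.9% before thinning (median depths 7642 and 12303 UMIs; 90 and 10 cells left out). Bulge-like cells, which the CD34 gate should have depleted, had 6.86% and 13.9% (11.8% and 25.2% before thinning, at median depths of 5940 and 7051 UMIs) and a Birc5 ratio of 6.19 (3.52 to 11.9). Melanocyte-like cells, where a Krt14-driven transgene should be silent, had 7.48% and 48.0% (18.7% and 57.6% before thinning, at median depths of 9066 and 11795 UMIs). The melanocyte-like cells also held Krt14, a keratinocyte gene, at 17935 and 19490 CPM, above the 12930 and 15313 CPM of all kept cells. Their Birc5 level in the GOF library, 664 CPM, was near the 670 CPM of GOF barcodes left out by the cell filter. Of these 4516 barcodes 1371 failed only on mitochondrial share, so they do not stand for free RNA alone. Bulge-like GOF cells had 99.1 CPM of Birc5. The source of Birc5 in melanocyte-like cells was not tested. The other members of the passenger complex were lower in the GOF library. Aurkb, its kinase, was at 36.3 and 28.1 CPM, Incenp at 44.2 and 36.6 CPM, and Cdca8 (borealin) at 88.2 and 68.2 CPM. The median log2 ratio of the complex, Birc5 included, was -0.32. Among the inhibitor of apoptosis relatives Xiap was 1.27-fold and Birc6 1.12-fold higher, with a list median of 0.11 at percentile 56.8 of the random lists. Smo, the gene of which SmoM2 is an active form, was at 83.5 and 80.8 CPM. Whether the SmoM2 transcript adds to that count is not given in the sources used here.

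**Figure D1:**
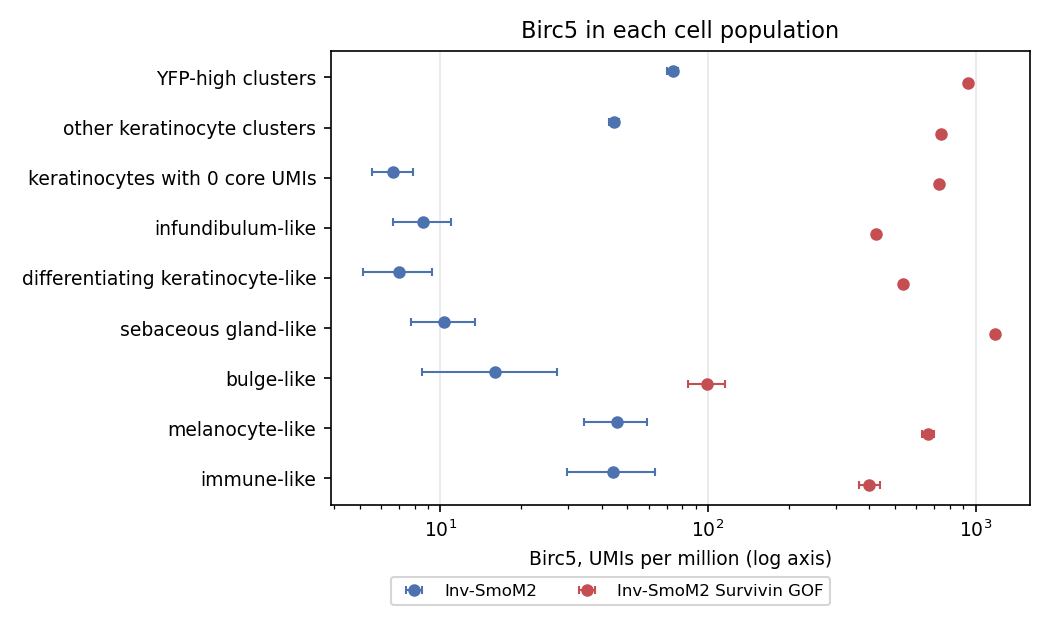
Birc5 counts (CPM) in 9 cell populations of the control library (blue) and the GOF library (red), on a log axis, with exact Poisson 95% intervals for counting error. The red point lies to the right of the blue point in every population plotted, with ratios from 6.19 in bulge-like cells to 115 in sebaceous gland-like cells.

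The rule of size left out sex genes such as Xist. Among the genes that passed it and are reported here, the largest GOF excess over all keratinocytes after Birc5 was that of Akr1c18 (9.76-fold). Akr1c18 encodes a progesterone-inactivating hydroxysteroid dehydrogenase. It was followed by Myadm (9.19-fold), a membrane protein first found in myeloid cells, and Tsix (8.96-fold), the antisense RNA of Xist. In male-called cells the log2 ratio of Myadm was 3.10, that of Akr1c18 0.47 and that of Tsix -0.35, and Tsix overlaps Xist on the other strand. Myadm, Sncg and Tns1 are among the 40 leading genes of cluster 2, which held 38 control and 1449 GOF cells, and Psmb9 among those of cluster 23. The synuclein gene Sncg was 2.94-fold higher, the translation initiation gene Eif3j2 2.71-fold (a near-identical copy, Eif3j1, can share its reads), Ccdc122 2.53-fold, the synaptic scaffold gene Dlgap1 2.50-fold and the Rap regulator Sipa1l2 2.45-fold. Tns1 (tensin 1, a focal adhesion protein) was 2.36-fold higher, the immunoproteasome subunit Psmb9 2.15-fold (log2 0.07 in male-called cells) and Scel (sciellin, a cornified envelope precursor) 2.12-fold.

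Among the genes that passed the rule, with at least 20 CPM in the higher library, 2 reported here had the largest control excess. These were the retinoid-responsive Rarres1 and Baiap2l1, an adaptor between membrane curvature and actin, both 5.01-fold. They are among the 40 leading genes of control-only clusters 13 and 12, respectively. Baiap2l1 was at 118 and 23.5 CPM and its log2 ratio was -2.95 in male-called cells. Krt2, a keratin of suprabasal epidermis, was at 1659 and 512 CPM, Krt24 at 148 and 58.1 CPM, and the scavenger receptor Colec12 at 154 and 44.7 CPM. In male-called cells Krt2 and Krt24 stood further apart (log2 -3.10 and -2.77). Also lower, by 2.41- to 3.12-fold, were the esterase Aadac, the fatty acid transporter Cd36, the elongases Elovl3 and Elovl6, and Cidea, a lipid droplet protein. Of these, Elovl3, Elovl6 and Cidea belong to the sebaceous gland markers, and Elovl3, Cidea and Aadac are leading genes of control-only cluster 13. Their log2 ratios in male-called cells were nearer 0, at -0.60, -0.74 and -0.48, and that of Cd36 was -0.33. Vcan (versican, a matrix proteoglycan) was 2.47-fold lower.

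Hedgehog targets had a median log2 ratio of -0.17 over 10 measured members in all keratinocytes, at percentile 0.20 of the random lists. This pooled value mixes clusters in different shares. The YFP-high clusters, where the median had the other sign, made up 30.7% of control and 21.3% of GOF keratinocytes outside the control-only clusters. How far these shares set the pooled median, Ptch1 and Gli1 was not tested. Ptch1, the receptor that hedgehog signalling itself induces, was at 188 and 153 CPM, and the transcription factor gene Gli1 at 29.4 and 18.8 CPM. Ccnd2 (cyclin D2) went the other way, at 273 and 500 CPM, as did Hhip, a hedgehog-binding decoy, at 29.0 and 40.9 CPM (log2 -0.39 in male-called cells). Embryonic hair follicle progenitor genes had a median of -0.02, with Tnfrsf19 at 1.60-fold and the matrix protein gene Tnc at 87.9 and 41.7 CPM. Wnt targets had a median of 0.14, with the stem cell marker Lgr5 at 36.2 and 18.3 CPM and Lgr6 at 11.3 and 16.9 CPM. Basal adhesion genes had a median of 0.07 that was -0.01 under median-of-ratios scaling. Early differentiation genes had a median of -0.21 (percentile 0.01), with Krt10, the first suprabasal keratin, at 4014 and 2843 CPM and the transglutaminase gene Tgm3 at 68.6 and 46.5 CPM. Late differentiation genes had a median of -0.44 (-1.48 in male-called cells), set by cornified envelope genes of the Lce1 family with few UMIs. Notch genes had a median of 0.12, with the Notch target Heyl at 0.465 and 0.909 CPM.

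Cell cycle genes parted by phase. S phase genes were higher in GOF keratinocytes, with a median log2 ratio of 0.23 over 39 members (percentile 99.9), and G2/M genes were lower, with a median of -0.29 over 51 members (percentile 0.00). Among S phase genes, Ccne2 (cyclin E2) was 1.55-fold, the helicase genes Hells and Mcm4 1.43- and 1.42-fold higher. Among G2/M genes, Ube2c and Cdc20, which drive the exit from mitosis, were at 139 and 71.4 CPM and at 84.3 and 43.9 CPM, and Ccnb1 (cyclin B1) was at 55.5 and 30.8 CPM. Ube2c and Cdc20 are also among the 40 leading genes of control-only cluster 12. At 3000 UMIs, 86.5% of control and 78.0% of GOF keratinocytes held at least 3 UMIs of the 51 genes. Without thinning the shares were 99.2% and 99.4%, a measure near its ceiling. With the 12 core genes the thinned shares were 26.8% and 15.3% (41.1% and 26.8% unthinned). Outside the 3 control-only clusters they were 20.9% and 15.2%, beside 3.39% and 0.433% in differentiating cluster 3, which should hold few dividing cells. Cyclin-dependent kinase inhibitors had a median of 0.25, with Cdkn2a, which encodes p16 and p19ARF, at 3.15 and 6.99 CPM.

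Cholesterol synthesis genes were lower in GOF keratinocytes, with a median log2 ratio of -0.73 over 19 members (percentile 0.00; -0.39 in male-called cells), and 14 of the 19 were lower by at least 1.5-fold. Mvd, an enzyme of the mevalonate pathway, was at 52.6 and 23.4 CPM, Insig1 2.14-fold lower and Msmo1 at 212 and 103 CPM. Insig1 is among the 40 leading genes of control-only cluster 12, and Mvd and Msmo1 among those of control-only cluster 13. Interferon response genes were higher, with a median of 1.12 over 13 members, led by Ifit1 at 0.465 and 3.15 CPM and Rtp4 at 0.354 and 2.03 CPM. MHC class I genes had a median of 0.62, with B2m (the light chain of class I molecules) at 147 and 262 CPM and H2-Q7 at 1.73 and 6.71 CPM. In male-called cells both medians were below 0, at -0.15 and -0.08. In GOF cells B2m was at 320 CPM in female-called and 168 CPM in male-called cells. Cluster 23, led by interferon-inducible genes, held 1 control and 67 GOF cells, and without it the interferon median was 0.80.

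Of the other lists, MAPK feedback genes had a median log2 ratio of -0.30, with the EGF receptor ligand Areg 3.03-fold lower. Glucocorticoid response genes had a median of -0.11, with Tsc22d3 (GILZ) 1.97-fold and Fkbp5 1.96-fold lower. Tsc22d3 is among the 40 leading genes of control-only cluster 12, and Areg among those of cluster 22, which held 88 control and 18 GOF cells. Immediate early genes stood at -0.11, glycolysis and hypoxia genes at -0.17, heat shock genes at -0.04, mitochondrial transcripts at -0.11 and ribosomal protein genes at -0.04. The ribosomal protein list was picked by the start of the gene name, which also takes in kinase genes of the Rps6k family. Apoptosis effectors had a median of 0.11. The anti-apoptotic Bcl2 family stood at 0.06, p53 targets at 0.13, Myc targets at 0.12, TGF-beta and BMP targets at 0.15, YAP targets at 0.05, extracellular matrix genes at 0.04, cytokines and chemokines at -0.01 and stressed keratinocyte genes at 0.18. In male-called cells the last 3 stood at -0.32, -0.27 and -0.04, and mitochondrial transcripts at 0.01.

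The YFP-high clusters held the basaloid-like clusters 9, 10 and 14 and cycling cluster 11. In cluster 10, 11 of 14 hair follicle progenitor or basaloid markers and 4 of 5 inner hair follicle markers were at least 2-fold up, and its 10 leading genes held 0 of the former and 1 of the latter. Cluster 9 made up 35.1% of these cells in the control and 17.3% in the GOF library, and cluster 10 20.9% and 37.2%, so the pooled values mix the clusters in different shares. Over the YFP-high clusters Birc5 was 12.7-fold higher (12.1 to 13.4), at 73.8 and 941 CPM. Hedgehog targets had a median log2 ratio of 0.20 (percentile 97.1), with Ccnd2 1.96-fold, Foxe1 1.46-fold, Mycn 1.41-fold and Hhip 1.35-fold higher. Within clusters 9, 10, 11 and 14 the hedgehog medians were nearer 0, at 0.15, 0.07, 0.04 and 0.03. Wnt targets had a median of 0.17, with the Wnt effector Lef1 1.93-fold and the feedback inhibitor Nkd1 1.81-fold higher, and Lgr5 at 109 and 66.6 CPM. Cux1, a hair follicle transcription factor, was 1.96-fold higher, while the median of embryonic hair follicle progenitor genes was -0.09 (0.02 in male-called cells). Lef1, Cux1 and Mycn are among the 40 leading genes of cluster 10, so its larger share in the GOF library can raise their pooled ratios. Basal adhesion genes had a median of -0.22, with the hemidesmosome components Col17a1 and Itgb4 at 497 and 334 CPM and at 135 and 95.6 CPM. YFP itself was at 32.5 and 30.4 CPM and Smo at 164 and 171 CPM. In the other keratinocyte clusters, the control-only ones left out, YFP was at 3.67 and 1.17 CPM although the sort asked for YFP, and control cells of the control-only clusters had 11.97 CPM.

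Early differentiation genes were lower in the YFP-high clusters of the GOF library, with a median log2 ratio of -1.04 over 15 members and 12 of them lower by at least 1.5-fold. Krt10 was at 1281 and 449.8 CPM, Krtdap at 1731 and 684 CPM and Calm5 at 23.5 and 7.36 CPM. Within clusters 9, 10, 11 and 14 the medians were -0.96, -0.62, -0.95 and -1.02. Late differentiation genes had a median of -1.66, with 47.5% of the UMIs of Lce1a1 and 51.8% of those of Lce1c in 1 cell. In the same clusters 17 markers of sebaceous gland and tail scale had a median of -1.11 and 14 of the 17 were lower. Some of these are expressed by the YFP-high cells too, such as Ldhb, at 112% and 106% of its library level. G2/M genes had a median of -0.25 and S phase genes 0.08. The thinned share of cells positive for the 12 core genes was 31.4% and 24.5% (44.0% and 39.3% unthinned, median depths 7801 and 14038 UMIs). Cdkn2a was 2.60-fold and its neighbour Cdkn2b 1.94-fold higher. Cholesterol synthesis genes had a median of -0.57 (-0.55 in male-called cells).

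The genes named for the YFP-high clusters included Tchh, the inner root sheath protein trichohyalin, 5.78-fold higher with 25.3% of its UMIs in 1 cell. Tchh is a leading gene of cluster 10, which is the largest part of these cells in the GOF library, and its log2 ratio was 3.64 within that cluster and 0.56 within cluster 9. Others higher in the GOF library were Tsix (5.36-fold), Myadm (5.15-fold), the pyrophosphatase Enpp1 (3.19-fold), Cilp (2.88-fold), the calcium channel gene Cacna1d (2.74-fold), Aebp1 (2.66-fold) and H2-M2 (2.62-fold). Cilp is among the 40 leading genes of cluster 10 and Enpp1 among those of cluster 14, both larger parts of these cells in the GOF library. In male-called cells Tsix was at 0.04. Lower were Fa2h, a fatty acid hydroxylase (9.45-fold), Krt24 (7.23-fold), Baiap2l1 (6.86-fold), the growth factor binding protein Igfbp2 (6.77-fold), Krt2 (5.60-fold), the lipase Mgll (5.01-fold), Sdr16c6 (4.34-fold), Mgst1 (3.83-fold), Cstdc5 (3.82-fold), Colec12 (3.70-fold) and Krt36 (3.59-fold). The lower genes named here mark clusters outside the YFP-high ones. Fa2h, Mgll, Sdr16c6 and Mgst1 are among the 40 leading genes of sebaceous gland-like cluster 17, Krt2 and Cstdc5 of differentiating cluster 3, Krt24 and Krt36 of cluster 6, Igfbp2 and Colec12 of cluster 5, and Baiap2l1 of control-only cluster 12.

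**Figure D2:**
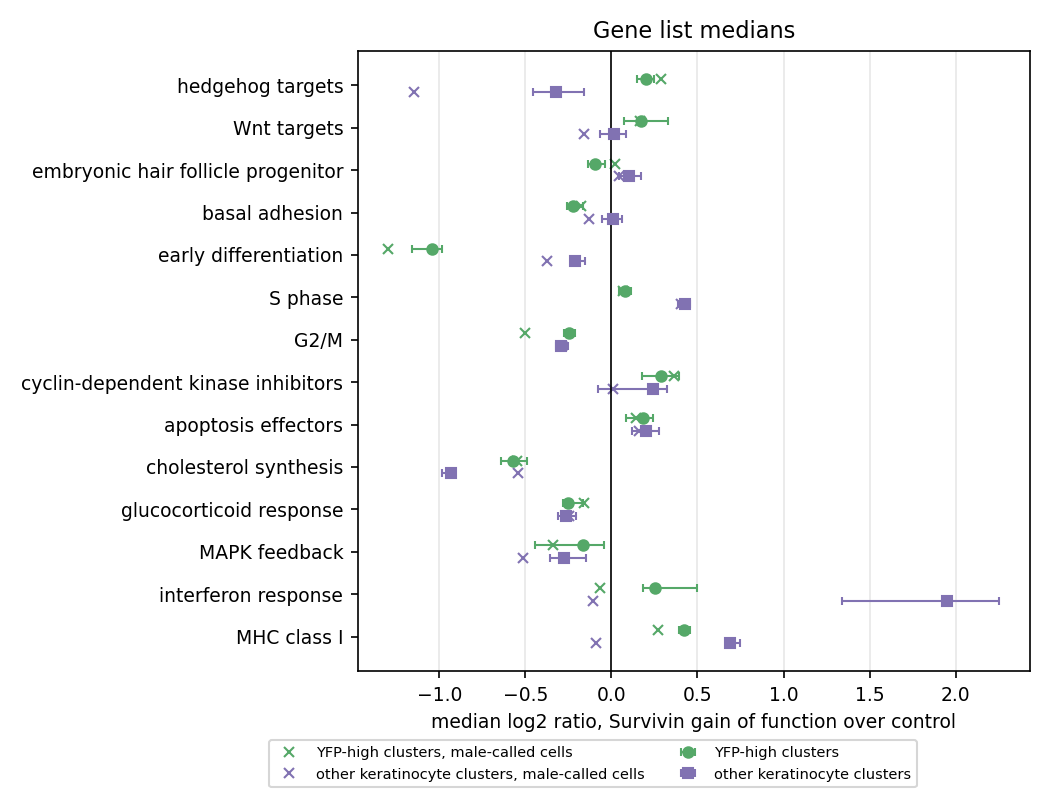
Median log2 ratio (GOF over control) of 14 gene lists in the YFP-high clusters (green circles) and in the other keratinocyte clusters (purple squares), with intervals from resampled counts; crosses give the medians in male-called cells. Early differentiation lies at -1.04 in the YFP-high and -0.21 in the other clusters, and the interferon response medians of 0.25 and 1.95 move to -0.06 and -0.11 in male-called cells.

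Sebaceous gland-like cells (cluster 17; 305 control and 231 GOF cells) had higher cell cycle genes in the GOF library. G2/M genes were higher in the GOF library in 47 of 48 measured members, with a G2/M list median in sebaceous gland-like cells of 1.26 (0.53 under the strict filter), and the 35 S phase genes had a median of 1.31, with Tyms lowest at 1.003-fold (0.888 to 1.13). The matched random lists had medians of 0.27 and 0.29 in this class, and under median-of-ratios scaling the G2/M and S phase medians were 0.998 and 1.06. The proliferation marker Mki67 was at 32.1 and 139 CPM (4.34-fold, 3.67 to 5.16), the topoisomerase gene Top2a at 30.6 and 117 CPM and the ribonucleotide reductase gene Rrm2 at 12.3 and 49.2 CPM. At 3000 UMIs, 13 of 304 control cells (4.28%, 2.30 to 7.20) and 38 of 231 GOF cells (16.5%, 11.9 to 21.9) were positive for the core genes, and 16.1% and 38.1% without thinning. In male-called cells the shares were 4.297% (2.16 to 7.56) and 11.3% (6.16 to 18.6), intervals that overlap, and female-called GOF cells had 24%. With called doublets kept, the shares were 9.23% (6.36 to 12.8) and 15.6% (11.4 to 20.4), which overlap too, and the G2/M median was 0.81. Cholesterol synthesis genes were lower in 18 of 18 members (median -0.91), and extracellular matrix genes had a median of 1.07 (0.37 in male-called cells).

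**Figure D3:**
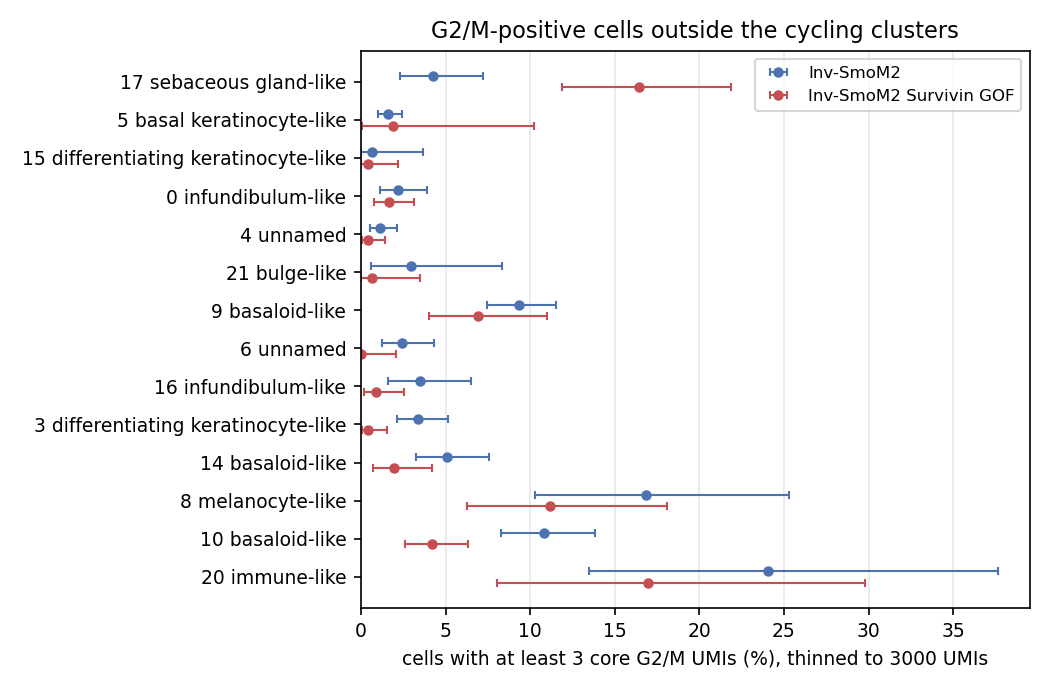
Share of cells (%) with at least 3 UMIs of the 12 core G2/M genes after thinning to 3000 UMIs, per cluster outside the cycling clusters, for the control (blue) and GOF library (red), with exact binomial 95% intervals. Sebaceous gland-like cluster 17 has the widest gap in the GOF direction, 4.28% against 16.5%; called doublets are left out.

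Infundibulum-like cells (clusters 0 and 16) were named for the upper hair follicle. Cluster 0 held 501 of the 762 control and 538 of the 881 GOF cells of this class. It had 3 of 14 infundibulum markers at least 2-fold up and 0 among its 10 leading genes, while cluster 16 had 12 of 14 up. In the class hedgehog targets had a median log2 ratio of -0.51, with 7 of 9 lower, and cholesterol synthesis genes a median of -0.45, with 19 of 19 lower. In cluster 0 the sebaceous gland and tail scale markers had a lower median still, -1.24 over 16 members. S phase genes had a median of 0.30 and G2/M genes -0.20. In differentiating keratinocyte-like cells (clusters 3 and 15) hedgehog targets had a median of -1.32 over 9 members, cholesterol synthesis genes -0.68, with 19 of 19 lower, S phase genes 0.32 and G2/M genes -0.52. Early differentiation genes stood at -0.16 in the infundibulum-like and -0.12 in the differentiating class. YFP was high in the clusters rich in hedgehog targets, but also in control cells of cluster 22, where 0 of 10 basaloid markers were at least 2-fold up. It was lower in the GOF library in both classes as well, at 2.99 and 0.808 CPM in infundibulum-like and at 5.02 and 0.639 CPM in differentiating keratinocyte-like cells.

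The sort, the cell filter and the depth of the libraries can all set the shares of cell classes. YFP-high cells made up 24.3% of kept control and 20.7% of kept GOF cells, a difference of -3.61 percentage points (-4.90 to -2.31). Infundibulum-like cells made up 7.44% and 13.6%, differentiating keratinocyte-like cells 3.44 points more of the GOF library than of the control (7.58%), and sebaceous gland-like cells 2.98% and 3.56%. With at least 2000 genes the last pair of differences had the other sign. Control-only cluster 13 (213 control cells and 1 GOF cell) was left unnamed, and so out of the sebaceous gland-like class and its comparisons. In it, 12 of 15 sebaceous gland markers were at least 2-fold up, so the class may leave out such cells of the control. Among keratinocytes without the control-only clusters, sebaceous gland-like cells made up 3.77% and 3.66% and YFP-high cells 30.7% and 21.3%. Of the differentiating keratinocyte-like clusters, cluster 3 made up 7.74% and 7.32% of these keratinocytes and cluster 15 1.85% and 4.02%. Cluster 15 had 4 of 13 differentiating and 4 of 14 infundibulum markers at least 2-fold up. Unnamed cluster 6, with 9 of 14 differentiating markers at least 2-fold up, made up 5.59% and 2.77%. The control-only clusters took 19.4% of the control library and 0.0462% of the GOF library.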

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

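All tests given here were chosen only after the results had been seen, except the doublet score and the single-cell share of the sebaceous gland-like class. Birc5 stood out in cells outside the comparisons. The GOF to control ratio was 14.6 in melanocyte-like and 9.1 in immune-like cells, and GOF barcodes left out by the cell filter held 669.7 CPM of Birc5, against 41.1 CPM in the control. Xist stood at 554.2 CPM in GOF keratinocytes and at 2.71 CPM in the control, where 7327 of 10079 keratinocytes were male-called and 30 female-called. The list medians of cytokines and chemokines and of hedgehog targets had opposite signs inside and outside the YFP-high clusters, with differences of -0.6 and 0.52. The cytokine median inside was -0.38, but 0.08 in male-called cells. No explanation was tested for these results. Neither difference was tested, and the requirement of opposite signs was set after the values had been seen.

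Cluster 12 held 1709 control cells and 2 GOF cells, with no cell type markers among its 10 leading genes. Its 40 leading genes held the cycling markers Cdc20 and Ube2c, the tail scale marker Krt36 and the bulge marker Angptl7. Its median UMI count was 0.915 of the control median, which argues against doublets of different cell types at usual depth, although its median doublet score was 1.38 times the library median. Droplets filled mainly with free RNA remain a candidate explanation. The cell-to-cell dispersion of cluster 12 (1.13) was 0.906 of the lowest of the 13 other control clusters, which just missed the bound of 0.9. Its CPM profile correlated more closely with the other control cells (0.989) than that of any of these 13 clusters (at most 0.986). A cell state of the control mice stays open, since library and genotype coincide.

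Early differentiation genes such as Krt10 and Krtdap were lower in the YFP-high clusters of the GOF library. The sex of the cells is argued against, with a median of -1.295 in male-called cells. More free RNA in the control library stays open: 17 sebaceous gland and tail scale markers had a median of -1.113, but these cells express some of them, and the free RNA estimated from them was 16.9% and 7.97% of library levels in the control and GOF library at the low, 20.1% and 20.2% at the middle and 45.7% and 62.1% at the high estimate. Taking it off left a median of -0.996 with 14 of 15 genes above it, of -2.062 with 5 genes, and 0 genes, respectively. Lower expression by the cells themselves thus cannot be told apart from free RNA: in 6 other clusters the early differentiation median lay nearer to 0 than that of the markers, such as -0.09 and -1.24 in cluster 0 and -0.39 and -0.51 in melanocyte-like cluster 8, but cells of most of these clusters could express the early genes themselves.

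G2/M genes such as Mki67 and Top2a were higher in sebaceous gland-like cells of the GOF library. Sex as the whole cause is argued against by a G2/M median of 1.174 in male-called cells, and 1 deep cell by the largest cell's 3.15% of the list's UMIs. That share does not bear on a small group of cells. Mki67 was at 557 CPM in the 38 G2/M-positive GOF cells and 38.7 CPM in the others, though Mki67 is 1 of the genes that set this split. Doublets as the source of all such cells are argued against by a test added later. Of the positive cells, 13.158% (4.41 to 28.1) held both Xist and Y-linked UMIs, against 53.5% expected of pairs with a random keratinocyte. Doublets as a part of the source stay open: the G2/M-positive GOF cells had 1.666 times the median doublet score of the others, past the bound of 1.5 set beforehand, but the control ratio was 3.91. With called doublets kept, 31 of 336 control and 42 of 270 GOF cells were positive, against 13 of 304 and 38 of 231 without them, but the clustering and so the class membership differed too. The G2/M-positive cells held less of the sebaceous marker Scd1 than the others, at 1830 and 5616 CPM in the control and 1697 and 5048 CPM in the GOF library. Cidea in the other cells was at 1539 CPM in the control and 867 CPM in the GOF library. Whether the mix of cells within this class differed between the libraries was not tested. More cycling with raised Survivin stays open, untested: male-called GOF cells had more Birc5 than female-called ones (1605 and 603 CPM) but the lower positive share (11.3% and 24%).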

How the results depend on the processing

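Comparisons of male-called cells, of cells with at least 2000 genes, of cells outside the control-only clusters and with the 12 core genes, and all alternatives for the YFP-high and sebaceous gland-like cells, were chosen after the data had been seen. The other alternatives were planned. For the 18 results that answer a comparison, 162 alternative values were computed, of which 83 stayed within counting error of the reported value, 75 moved and 4 reversed. A reversal is a change of sign in a gene with at least a 1.5-fold ratio, in a list median of at least 0.1 from 0, or in a share difference whose interval leaves out 0. For 135 named genes, 679 of 1210 values stayed, 510 moved and 21 reversed. For the 26 other lists, 159 of 260 stayed, 89 moved and 12 reversed. Counting smaller reported values too, the sign was the other one in 10, 44 and 33 values, respectively. Where a value moved or reversed, the cause was not tested unless stated.

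Birc5 was higher in the GOF library under every alternative run. The Birc5 log2 ratio in keratinocytes (3.84) was 3.76 with at least 2000 genes, 6.97 in basal keratinocyte-like clusters alone, 3.80 with called doublets kept, 4.03 in male-called cells, 3.76 under median-of-ratios scaling, 3.48 under the strict filter and 3.88 without the control-only clusters. The Birc5 log2 ratio in cells without other G2/M transcripts, here those with 0 UMIs of the 12 core genes because the whole list left 8 and 4 cells, was 6.79. It was 7.09 with at least 2000 genes, 6.43 with cells weighted equally, 6.17 under the lenient filter, 7.23 in male-called cells and 7.62 under the strict filter. The Birc5 log2 ratio in YFP-high clusters (3.67) was 3.77 with cells weighted equally and 3.37 under the strict filter.

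The G2/M cell share difference (-8.52 points) was -11.55 with the 12 core genes, -4.62 with at least 2 UMIs, -17.01 with at least 6 UMIs, -9.91 in male-called cells, -11.3 under the strict filter and -5.70 without the control-only clusters. It was -2.06 at 5000 UMIs and reversed to 0.27 in unthinned cells, where nearly every cell is positive. The G2/M list median (-0.29) was -0.36 with at least 2000 genes, -0.035 in basal keratinocyte-like clusters, -0.26 with doublets kept, -0.43 with cells weighted equally, -0.24 under the lenient filter, -0.47 in male-called cells, -0.37 under median-of-ratios scaling, -0.47 under the strict filter and -0.35 without the control-only clusters. The G2/M list median in YFP-high clusters (-0.25) was -0.42 with cells weighted equally, -0.50 in male-called cells, -0.32 under scaling and -0.43 under the strict filter. The G2/M list median in sebaceous gland-like cells (1.26) was 0.81 with doublets kept, 1.17 in male-called cells, 0.998 under scaling and 0.53 under the strict filter. The S phase list median in sebaceous gland-like cells (1.31) was 0.97 in male-called cells and 1.06 under scaling.

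The hedgehog targets list median (-0.17) was -0.45 in basal keratinocyte-like clusters and -0.25 under median-of-ratios scaling. The hedgehog targets list median in YFP-high clusters (0.20) was 0.29 in male-called cells, 0.13 under scaling and 0.12 under the strict filter. The early differentiation list median (-0.21) was -0.16 in basal keratinocyte-like clusters, -0.38 in male-called cells, -0.30 under scaling, -0.13 under the strict filter and -0.15 without the control-only clusters. The early differentiation list median in YFP-high clusters (-1.04) was -0.87 with doublets kept, -1.31 under the lenient filter, -1.295 in male-called cells and -0.76 under the strict filter. The embryonic hair follicle progenitor list median (-0.02) was -0.38 in basal keratinocyte-like clusters and -0.12 without the control-only clusters. The basal adhesion list median (0.07) was -0.12 in basal keratinocyte-like clusters, -0.042 in male-called cells, -0.01 under scaling and -0.0 without the control-only clusters, so it has no settled direction. Scaling moved the median of all keratinocyte genes by 0.08.

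Cell class shares depended on the filter. Of the cell class shares, YFP-high (-3.61 points) was -5.19 with at least 2000 genes, -9.4 under the lenient filter, -5.77 in male-called cells and -9.45 without the control-only clusters. Of the cell class shares, differentiating keratinocyte-like (3.44) was 0.53 at Leiden resolution 0.5, 0.29 under the lenient filter, 5.03 under the strict filter and 1.62 without the control-only clusters, and reversed to -0.48 with at least 2000 genes. Of the cell class shares, infundibulum-like (6.12) was 10.25 at Leiden resolution 0.5, 8.33 with at least 2000 genes, 9.7 under the lenient filter, 10.22 in male-called cells, 3.34 under the strict filter and 4.33 without the control-only clusters. Of the cell class shares, sebaceous gland-like (0.58) was 2.83 in male-called cells and reversed to -0.05 with at least 2000 genes and to -0.14 without the control-only clusters.

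Reversals in basal keratinocyte-like clusters, which are mostly cluster 5 in the control and cluster 2 in the GOF library, were Adm, Lce1b and Lce1m (each 1.12), Cxcl10 (-0.75), Cxcl9 (-0.115), Defb3 (-1.88), S100a9 (-0.76), Sprr2d (-0.20), Vim (0.14), Wif1 (0.12), Zeb2 (0.70), Wnt targets list median (-0.039), chromosomal passenger complex list median (0.069), glycolysis and hypoxia list median (0.096), late differentiation list median (0.061) and stressed keratinocyte list median (-0.76). In male-called cells, where Hhip also had the other sign (-0.39 against 0.50) from a ratio below 1.5-fold, reversals were Cxcl10 (-0.088), Cxcl9 (-0.63), H2-Q7 (-0.16), Ifit1 (-2.80), Oasl2 (-0.27), Rtp4 (-0.999), Tsix (-0.35), MHC class I list median (-0.084), interferon response list median (-0.15), mitochondrial transcripts list median (0.014) and stressed keratinocyte list median (-0.041). Under the lenient filter Lce1a1 (0.23), Lce1b (0.52), Lce1c (0.075) and late differentiation list median (0.49) reversed, under the strict filter mitochondrial transcripts list median (0.053), and with cells weighted equally stressed keratinocyte list median (-0.14).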

Other observations

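The values here were looked at only after the main comparisons had been seen. Sebaceous gland-like cells of the GOF library had higher YAP target genes (median log2 ratio 1.17 over 7 members) and chromosomal passenger genes (1.53 over 4 members), with 0.56 and 1.49 in male-called cells. The passenger list holds Birc5 itself, and its members Aurkb and Cdca8 are also in the G2/M list. Its median thus largely repeats the G2/M result of this class and is no separate finding. Cluster 23, which held 67 GOF cells and 1 control cell, had 61 female-called and 0 male-called GOF cells and carried 10.6% of the UMIs of the interferon response list.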
